A study of Caenorhabditis elegans with 2 samples.

How the data were processed

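The data were peak lists from ChIP-seq of eGFP-tagged ZTF-7 in whole L4 larvae, from 2 biological replicates of 1 group, with a size range of 150 to 350 bp per the labels. Each replicate had a list of 30000 regions on each of 2 genome builds, ce10 and ce11, and so did the pooled replicates. A further list per build was deposited as the peaks past the IDR threshold. Per the notes deposited with the files, the region lists derive from the ChIP alignments and from 1 further file, from which the control-normalised signal tracks also derive and which was taken to be the control. The IDR list derives from the pooled list and both replicate lists. The peak caller, its version, the aligner and the IDR cutoff are not given in the sources used here.

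The deposited signal values are the peak caller's own signal per peak and compare only within a list. The deposited q-values are given as −log10 q. All 1311 IDR peaks had the same value, 2.11, which is the list's ceiling, so peaks were ranked by signal. The p-value column held no values. No read counts were in the files used, so the depth per sample is unknown. The IDR list on ce11 had 4 repeated intervals with different summits and 1 summit outside its interval, which were kept.

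Build ce11 is WBcel235, and no interval passed a chromosome end of that reference. Genes and biotypes came from Ensembl release 115, sequence from the RefSeq copy of the same assembly, and symbols of mitochondrial coding genes from RefSeq by overlap. The ce10 lists served for counts, replicate overlap and the share on X, with the chromosome lengths of WBcel235, and no coordinates were converted.

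A gene counted as bound if an IDR summit lay within 1000 bp of its 5' end. Promoter share was compared with 1000 circular shifts of the summits along each chromosome, and replicate overlap with 1000 shifts of 1 list. The N strongest regions, with N = 1311, were compared, and the rank correlation used 100000 resamples (10000 over all pooled regions). X was compared with the autosomes by an exact binomial test with exact 95% intervals. The 36 gene lists were fixed before the data were examined and tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists by name had protein-coding genes as background. Spliced leader genes and lists by biotype had all genes other than piRNA, and the piRNA list all genes. Where each summit was given only to its nearest 5' end, the nearest was taken within the list's background. A summit could thus count for both a coding and a non-coding gene. An alternative with 10000 shifts used the list's share of all bound genes. A first version of it used the log odds ratio and was replaced after its results were seen, because it gave lists with 0 bound members the smallest possible p by construction. Signal at lists with at least 10 peaks was tested with 100000 resamples.

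Each 6-mer was tested by an exact sign test of peaks with it only within 50 bp of the summit against peaks with it only in the flanks. The flanks ran from 250 to 302 bp on either side, so that both held 96 6-mer positions. Genes named were those with a 5' end within 1000 bp of the summit of the 20 strongest IDR peaks overlapped by the 2622 strongest regions of both replicates, the 4 members of highest signal of each list past the threshold, and ztf-7 and unc-119.

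The tests were run on simulated data. Of 40 sets of uniform summits, 1 had a promoter share with p under 0.05. All 20 lists of 200 genes drawn 5 times as often passed, as did 1 of 400 unchanged lists. The simulated lists held genes drawn at random, so they do not cover lists of neighbouring genes that share a peak. On uniform summits 0 6-mers passed, and a planted 6-mer ranked first. Uniform summits were placed without regard to GC content, so they do not cover the GC difference seen at the IDR summits. Alternatives were ce10 lists, stronger peaks, other windows, overlaps, backgrounds and assignments, and each replicate alone. Nuclear peaks only, peaks supported by both replicates, genes other than piRNA, the correlation over all pooled regions, signal from each replicate alone, and the X ratio split by distance, against chromosome length and against the bases at that distance, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.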

Results

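Binding of ZTF-7, a zinc-finger protein of the nematode Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA bound to a tagged protein is recovered and sequenced. The protein carried an eGFP tag and was expressed from an integrated transgene in strain OP332, an unc-119 mutant background. Whole L4 larvae of mixed sex gave 2 biological replicates of 1 group. No control sample was analysed here, so no comparison between conditions was possible, and the results describe where the peaks lay and how far the replicates shared them. The number of reads behind each list is unknown from the files used. Coordinates are those of build ce11 (WBcel235), counted from 1.

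The authors' list of peaks past their reproducibility threshold (IDR, the irreproducible discovery rate) held 1311 peaks, of which 1289 lay on nuclear chromosomes and 22 on mitochondrial DNA. Mitochondrial peaks had higher signal values as a group, with a median of 602 against 66.0 for nuclear peaks. The weakest mitochondrial peak ranked 266. The first 11 ranks were all mitochondrial, led by a peak over CYTB, which encodes cytochrome b of the respiratory chain, with a signal value of 3573. IDR peaks had a median width of 324 bp (81 to 1121 bp), and the list on build ce10 held 1288 peaks. Signal values are the peak caller's own and rank peaks only within a list. All 1311 IDR peaks were also in the pooled list with the same interval and signal, and exactly 1311 pooled regions had a signal at or above that of the weakest IDR peak. The IDR list was thus the strongest part of the pooled list. Not every peak in it was found in each replicate, as 1279 had a region in both replicate lists.

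The strongest peaks shared by both replicates were named by a rule set before the data were examined, which took the 20 of highest signal. Mitochondrial DNA held 14 of them. They included peaks by CYTB, ND2, ND3, COX1 and COX2, all subunits of respiratory chain complexes, and by tRNA genes. The 5 nuclear genes named by the rule were F44E7.13, F45B8.9, K02F3.15, C49G7.10 and Y58A7A.3. The F44E7.13 peak, on chromosome V from 5780708 to 5781035, had a signal of 639.2 and its summit lay 11 bp from the 5' end of this non-coding RNA gene, in an annotated 5' UTR. The F45B8.9 peak, on chromosome X from 14946433 to 14946718, had a signal of 422.8 and an intergenic summit. The peak near the snoRNA gene K02F3.15, on chromosome III from 833781 to 834045, had a signal of 420.1 and an intronic summit. Intergenic summits lay 51 bp upstream of the coding gene C49G7.10 and 240 bp upstream of the coding gene Y58A7A.3, both on chromosome V, with signals of 408.2 and 405.9. The remaining peak of the 20, on chromosome II from 13954120 to 13954418 with a signal of 628.3 and an intronic summit, lay 2833 bp from the nearest 5' end, that of C47F8.9, and gave no named gene.

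Among further nuclear peaks, chosen after their values were seen, the lbp-3 peak on chromosome X from 3256827 to 3257094 had a signal of 375.2. Signals of 286.1 and 265.1 were found upstream of rpl-3 and rpl-12, which encode proteins of the large ribosomal subunit. The peak upstream of ugt-13, a predicted UDP-glucuronosyltransferase gene, had a signal of 266.9.

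Replicates were compared by overlap and by rank. Of the 1311 strongest regions of replicate 1, 651 (49.7%) were overlapped by at least 1 bp by the 1311 strongest of replicate 2, against 2.16% on average over 1000 circular shifts (two-sided permutation p = 0.002, the smallest the shifts can give). Among the 1311 strongest regions of both replicates were 634 IDR peaks (48.4%), while 271 were so in replicate 1 alone, 341 in replicate 2 alone and 65 in neither. Nearly all IDR peaks had a region in each replicate's full list, 1299 in replicate 1 and 1291 in replicate 2. The 2622 strongest regions of both replicates covered 1042 IDR peaks (79.5%). Across the 1279 IDR peaks found in both lists, the replicate signals had a Spearman correlation of 0.220 (two-sided permutation p = 2e-05, the smallest the resamples can give). Peaks are not independent replicates. The IDR peaks are also the regions of highest pooled signal, and such selection can itself lower a correlation between replicates. The correlation was 0.474 over the 12991 pooled regions found in both lists, a set chosen after seeing the data, and 0.101 when a reciprocal overlap of 50% was required.

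**Figure D1:**
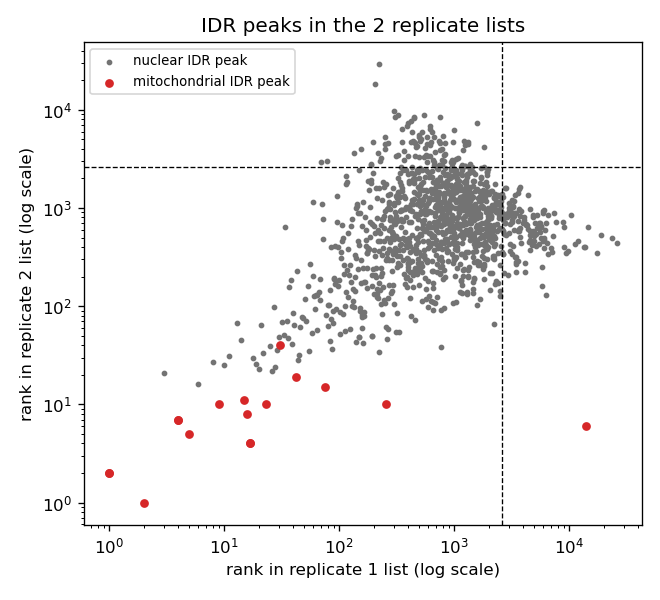
Rank of each IDR peak by signal in the replicate 1 list (x axis) and the replicate 2 list (y axis), both on log scales, for the 1279 peaks present in both lists. Red points are mitochondrial peaks and grey points nuclear ones, dashed lines mark rank 2622, and 1042 peaks rank within it in both lists.

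IDR summits lay mostly beside genes. Of 1311 summits, 1082 (82.5%) were within 1000 bp of an annotated gene 5' end, against 49.7% ± 1.44 (SD over 1000 circular shifts; two-sided permutation p = 0.002, the smallest possible). With protein-coding genes alone the share was 64.5%, against 34.7% for shifted summits. Pooled regions outside the IDR peaks had 54.2% near a 5' end. Nuclear summits were intergenic in 876 cases (68.0%, against 33.8% for shifted summits) and lay in coding exons in 15 cases (1.16%, against 24.2%). Introns held 16.6% of summits against 34.0% for shifted ones, and exons of non-coding genes held 9.46% against 3.17%. Each of these annotation shares had a two-sided permutation p of 0.002, the smallest possible. This breakdown was chosen after seeing the data.

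Chromosome X had the highest density of nuclear IDR peaks, 18.1 per Mb with a 95% Poisson interval of 16.2 to 20.2. Chromosome V had the lowest, 9.03 per Mb with an interval of 7.79 to 10.4. Of the 1289 nuclear peaks, 321 (24.9%) lay on X, against 17.7% expected from length (exact binomial p = 8.59e-11, two-sided). The X to autosome density ratio was 1.54 with an exact 95% interval of 1.36 to 1.75. It was 1.35 in the strongest peaks of replicate 2 alone and 1.69 in those of replicate 1 alone. X peaks lay near coding genes less often than autosomal ones, with 157 of 321 (48.9%) against 669 of 968 (69.1%) within 1000 bp of a protein-coding 5' end (Fisher's exact p = 1.35e-10, two-sided, chosen after seeing the data). Pooled regions outside the IDR peaks went the same way, with 30.9% on X and 37.2% on the autosomes, and X holds 13.7% of the coding genes. For the 826 peaks within 1000 bp of a coding 5' end the X to autosome ratio was 1.36 (exact 95% interval 1.14 to 1.62) against the bases at that distance, and 1.09 (0.913 to 1.30) against chromosome length. For the 463 peaks farther away it was 2.30 (1.89 to 2.79) and 2.56 (2.10 to 3.10). This split and both its expectations were chosen after seeing the data. All intervals cover counting error only, and neighbouring peaks are not independent.

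**Figure D2:**
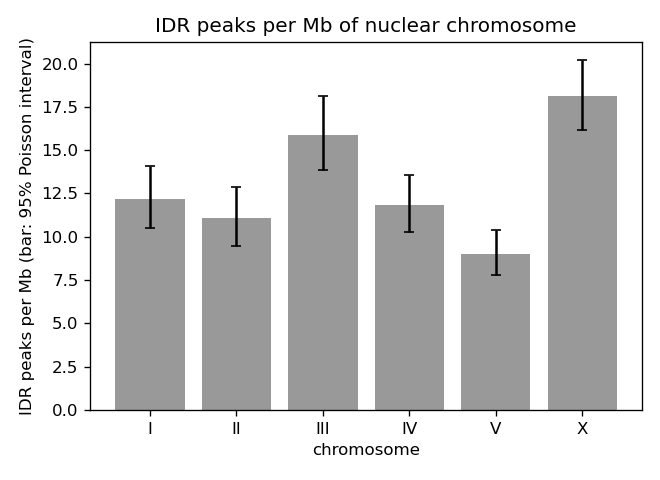
IDR peaks per Mb (y axis) on each nuclear chromosome (x axis), with 95% Poisson intervals as bars. Chromosome X stands at 18.1 per Mb and chromosome V at 9.03 per Mb.

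Cytosolic ribosomal proteins, translation factors, chaperones and nuclear-encoded oxidative phosphorylation genes had IDR peaks more often than other protein-coding genes. The ribosomal protein genes led, with a summit within 1000 bp of the 5' end in 39 of 81 (48.1%), against 5.44% of other protein-coding genes (log2 odds ratio 4.01, Fisher's exact test with Benjamini-Hochberg adjusted p = 1.06e-26). By the same exact test, translation factors had a summit at 13 of 39 (33.3%, adjusted p = 4.2e-07), chaperones and heat shock genes in 19 of 59 (32.2%, adjusted p = 1.23e-09) and nuclear-encoded oxidative phosphorylation genes in 19 of 67 (28.4%, adjusted p = 1.21e-08). These 4 lists also passed when summits were shifted along the chromosomes, with adjusted permutation p from 0.0009 to 0.00288. With each summit given only to its nearest protein-coding 5' end, 21 of 81 ribosomal protein genes (25.9%) and 7 of 59 chaperone genes (11.9%) were bound. Other protein-coding genes stood at 4.05% and 4.12%, and both lists passed (exact test, adjusted p = 5.57e-11 and 0.0297).

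The ribosomal protein genes with the strongest peaks were rpl-3, rpl-12, rpl-20 and rps-23, with signals from 286.1 to 215.4 and intergenic summits 26 to 287 bp upstream. Among translation factors the strongest were eef-1A.2 (310.9), eif-3.C (159.4), eef-1A.1 (118.9) and iff-2 (114.9). The eef-1A genes encode the elongation factor that brings aminoacyl-tRNA to the ribosome. Chaperone genes were led by hsp-110, cct-8, cct-1 and hsp-60, with signals from 147.0 to 102.0; cct genes encode subunits of the cytosolic chaperonin. The hsp-110 peak, on chromosome III from 8447104 to 8447241, was also the peak of the proteasome gene rpn-3, whose 5' end faces it from the other side. Oxidative phosphorylation genes were led by cox-5A (198.5), ucr-2.2 (114.3), cox-6A (109.3) and atp-1 (101.0).

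Both tRNA and snoRNA genes were bound more often than other genes. A summit lay within 1000 bp of 201 of 634 tRNA genes (31.7%, against 5.57% of other genes; Fisher's exact test, adjusted p = 2.81e-88) and of 91 of 346 snoRNA genes (26.3%, adjusted p = 1.47e-32). Both passed under shifted summits, with adjusted permutation p of 0.0016 and 0.0009. With each summit given only to its nearest 5' end among genes other than piRNA, 126 of 634 tRNA (19.9%) and 57 of 346 snoRNA genes (16.5%) were bound. Other genes stood at 2.99% and 3.18%, and both lists passed (exact test, adjusted p = 1.15e-59 and 1.66e-22). The 201 tRNA genes lay by 156 separate peaks, and 179 of 612 nuclear tRNA genes (29.2%) were bound. The 4 tRNA genes of highest signal shared the mitochondrial peak over CYTB. The snoRNA genes of highest signal were K02F3.15, C06A1.9, F28D1.13 and ZK994.7, and the F28D1.13 peak was also that of rps-23. The summit lay 488 bp downstream of the 5' end of K02F3.15. For C06A1.9, F28D1.13 and ZK994.7 it lay 505, 684 and 47 bp upstream. Near-identical tRNA, spliced leader and snRNA gene copies can share reads, so which copy was bound is uncertain. Whether peaks at these lists or at the coding gene lists above are specific to ZTF-7 was not tested. No control sample was analysed here.

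Another 6 lists passed Fisher's exact test but not the test with shifted summits. Mitochondrial ribosomal proteins had a summit at 11 of 70 genes (exact test, adjusted p = 0.00435, and 0.105 with shifts), led by mrpl-23, mrps-7, mrpl-12 and mrpl-28. The proteasome had 7 of 33 (0.00486, and 0.0831 with shifts), led by rpn-3, rpn-11, rpn-2 and pbs-1. Spliceosome and splicing factors had 8 of 40 by 6 peaks (0.00408, and 0.0981 with shifts), led by prp-40, snr-4, rsp-3 and rnp-6. The rsp-3 and rnp-6 peaks ranked 4786 and 4600 in replicate 1, against 416 and 530 in replicate 2. Ribosome biogenesis and nucleolus genes had 5 of 23 (0.0179, and 0.0831 with shifts), led by rbd-1, nol-56, nol-58 and nol-10. The nol-56 peak ranked 2494 in replicate 1 and 264 in replicate 2. The nol-10 peak ranked 544 in replicate 1 and had no overlapping region in the replicate 2 list. Spliced leader RNA genes, which donate the 5' leader of trans-spliced mRNAs, had 9 of 30 (0.000165, and 0.0946 with shifts), led by sls-2.4, sls-2.2, sls-2.3 and sls-2.1. The sls-2.3 peak was that of sls-2.2, with its summit 735 bp downstream of the 5' end of sls-2.3. snRNA genes, a class that holds the spliced leader genes here, had 18 of 129 (0.00342, and 0.0974 with shifts), led by sls-2.4, R07E5.16, sls-2.2 and sls-2.3. In the strongest regions of replicate 2 alone, without replicate 1, the exact tests no longer called spliceosome (adjusted p = 0.0511), ribosome biogenesis (0.0752), spliced leader (0.0549) or snRNA genes (0.154). Without replicate 2 the exact tests no longer called mitochondrial ribosomal proteins (adjusted p = 0.157) or ribosome biogenesis (0.0629). The log2 odds ratio of ribosome biogenesis genes was 2.33 in the IDR list, 2.01 without replicate 1 and 2.10 without replicate 2, and that of mitochondrial ribosomal proteins was 1.71 and fell to 1.13 without replicate 2. In the upper 50% of peaks by signal 1 of 33 proteasome genes was bound (exact test, adjusted p = 0.934), 3 of 70 mitochondrial ribosomal protein genes (0.787), 2 of 40 spliceosome genes (0.585) and 3 of 23 ribosome biogenesis genes (0.0722). The log2 odds ratios there were 0.623, 0.793, 1.12 and 2.52, so only that of ribosome biogenesis genes did not fall. Against genes with a pooled region nearby the exact tests no longer called mitochondrial ribosomal proteins (adjusted p = 0.176), the proteasome (0.164), spliceosome (0.115) or ribosome biogenesis genes (0.0503). Their log2 odds ratios there were 1.00, 1.41, 1.43 and 2.18. With nearest 5' ends only, the exact tests no longer called mitochondrial ribosomal proteins (adjusted p = 0.0657), spliceosome (0.175) or ribosome biogenesis genes (0.153). Peaks among the 2622 strongest of both replicates gave no call for mitochondrial ribosomal proteins (exact test, adjusted p = 0.0901) or ribosome biogenesis (0.165).

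Chemoreceptor genes, C-type lectins, cuticle collagens, pseudogenes and piRNA genes were bound less often. Chemoreceptor genes had a summit at 4 of 1308 (0.306%, log2 odds ratio -4.21, Fisher's exact test, adjusted p = 2.66e-27), namely srw-7, sri-5, srh-16 and sre-23. Pseudogenes had 17 of 2128 (0.799%, exact test, adjusted p = 4.16e-37) and piRNA genes 238 of 15363 (1.55%, adjusted p = 2.42e-126), the latter by 62 peaks. The exact tests treat genes as independent, although 1 peak can lie by several genes. With shifted summits chemoreceptor genes, pseudogenes and piRNA genes also passed (adjusted permutation p = 0.0009 for each), as did C-type lectins (0.0471). The piRNA count was 28 with nearest 5' ends only, 79 with the 500 bp window and 508 with the 2000 bp window. The piRNA share stayed below that of other genes in each. The piRNA genes of highest signal were 21ur-3824 and 21ur-3995, which shared a peak of signal 228.1, then 21ur-8796 and 21ur-10291. The shared summit lay 918 and 915 bp upstream of 21ur-3824 and 21ur-3995. C-type lectin genes had only clec-126 of 240 (exact test, adjusted p = 9.58e-05), a call that ended against genes with a pooled region nearby (adjusted p = 0.608). Cuticle collagens had 3 of 173, col-85, col-185 and col-173 (log2 odds ratio -1.54, exact test, adjusted p = 0.0412). The collagen call held without replicate 1 and with the 500 bp window (exact tests, adjusted p = 0.0180 and 0.0172). It ended under each of the other alternatives run, with adjusted exact or permutation p from 0.0589 to 0.321 and log2 ratios from -1.80 to -0.76. No summit lay by the 24 muscle, 24 neuron or 17 hypodermis and seam marker genes, and 1 of 23 intestine and 2 of 35 germ granule and germline genes had one; none of these 5 lists passed. Other lists that did not pass were nuclear hormone receptors (18 of 269), detoxification genes (13 of 185), F-box genes (11 of 322), microRNA genes (20 of 261), homeobox ceh genes (1 of 63), zinc-finger ztf genes (2 of 25) and histones (2 of 72). Aminoacyl-tRNA synthetases had 2 of 32, V-ATPase genes 3 of 20, the RNA exosome 1 of 13, DNA replication and cell cycle genes 5 of 44, sperm genes 0 of 63 and Argonaute genes 0 of 25. V-ATPase genes passed without replicate 2, with 5 of 20 bound (exact test, adjusted p = 0.00791), while without replicate 1 none of the 20 was bound (adjusted p = 0.767). With the 2000 bp window microRNA genes were bound more often (exact test, adjusted p = 0.00697), and sperm genes (0.0191) and F-box genes (0.0250) less often. In the upper 50% of peaks by signal DNA replication and cell cycle genes were bound more often (exact test, adjusted p = 0.0273). Of 22 rRNA genes the 2 mitochondrial ones were bound. In all, 12 of 36 lists were bound more often and 5 less often.

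**Figure D3:**
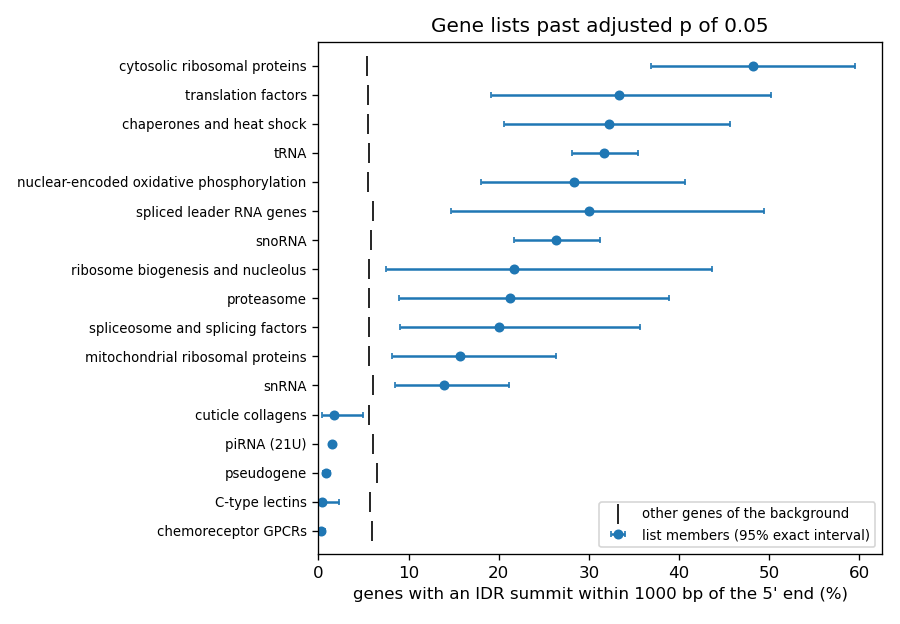
Percent of genes with an IDR summit within 1000 bp of the 5' end (x axis) for the gene lists past an adjusted p of 0.05 (y axis), with exact 95% intervals; black ticks give the other genes of each background. Cytosolic ribosomal protein genes stand at 48.1% and chemoreceptor genes at 0.306%.

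Peaks at cytosolic ribosomal protein genes were also stronger than other IDR peaks. Their median signal was 89.98 over 35 peaks, against 66.1 for the rest (permutation test, two-sided, adjusted p = 0.00588). It was the 1 list past the threshold among those with at least 10 peaks. Translation factor peaks had a median of 93.5 over 13 peaks (permutation test, adjusted p = 0.0593), snoRNA peaks 75.0 over 88 (adjusted p = 0.0546) and pseudogene peaks 91.5 over 16 (adjusted p = 0.0546). With nuclear peaks only, chosen after seeing the data, these lists passed too (permutation test, adjusted p = 0.0421, 0.0329 and 0.0329). Without replicate 1 they did not (permutation test, adjusted p = 0.138, 0.169 and 0.0612). Without replicate 2 only snoRNA peaks among them passed (permutation test, adjusted p = 0.00022).

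Sequence at the summits was rich in G and C. Within 50 bp of nuclear summits the GC content was 44.8% ± 8.78 (SD over 1289 peaks), against 34.8% ± 7.38 in the flanks (permutation p = 0.0002, two-sided, the smallest possible; chosen after seeing the data). Pooled regions outside the IDR peaks showed 31.7% at the summit and 34.2% in the flanks. The 6-mer GACGCA was present near 16.7% of summits and in 1.83% of flanks (adjusted exact p = 1.11e-38), GAGAGA near 24.7% and in 6.42% (4.96e-38), and GCGCAC near 10.5% and in 0.993% (1.29e-26). AAAATT went the other way, near 17.5% of summits and in 42.7% of flanks (1.57e-40). Of the strand-collapsed 6-mers tested, 506 were more frequent near the summit and 361 less. Without replicate 1 these numbers were 260 and 185. Among the 1053 IDR peaks away from tRNA, snoRNA and snRNA genes they were 414 and 318. Of those 414 6-mers, 392 were also more frequent over all IDR peaks tested. The counts were not corrected for the difference in GC content.

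The loci of the tagged gene and of the strain's marker gene unc-119 were examined because the strain carries a transgene. The ztf-7 gene, on chromosome V from 9786993 to 9789707 on the minus strand, had an IDR peak of signal 85.9 and rank 355, from 9789895 to 9790218, upstream of its 5' end. The peak ranked 403 in replicate 1 and 448 in replicate 2. No IDR peak overlapped unc-119, on chromosome III from 10902641 to 10908935, or the 1000 bp on either side; its strongest pooled region, from 10905065 to 10905388, ranked 3585. The strongest in replicate 1, from 10905194 to 10905497, ranked 491. In replicate 2 the strongest was another region, from 10908690 to 10908999, of rank 4607. The 40 kb around ztf-7 held 2 pooled regions per 10 kb, against a mean of 3.02 in 1000 random windows (two-sided permutation p = 0.789).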

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

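The alternatives with nuclear peaks only, with peaks among the 2N strongest of both replicates, with genes other than piRNA, with all pooled regions, with list signal from single replicates, and with the X ratio split by distance, with either expectation, were chosen after seeing the data. Replicate overlap, rank correlation, promoter share and the X to autosome ratio over all nuclear peaks kept their direction and their side of the threshold under each alternative run. Replicate overlap ranged from 42.6% to 50.1%. Promoter share ranged from 64.5% with protein-coding genes only (34.7% for shifted summits) to 91.6% with the 2000 bp window (72.8% for shifted summits). The X ratio ranged from 1.35 without replicate 1 to 2.09 with protein-coding genes in place of length as expectation. The rank correlation ranged from 0.101 to 0.474. Keeping the upper 50% of peaks by signal left 656 peaks by construction, and called 313 6-mers more frequent and 221 less frequent at the summit with fewer peaks tested. Without replicate 1 or without replicate 2, the more frequent 6-mers numbered 260 to 636 and the less frequent ones 185 to 423; the lower numbers came without replicate 1, and the cause was not tested. Lists bound more often numbered 8 without replicate 1, 11 without replicate 2 and 12 in the IDR list. They numbered 9 in the upper 50% of peaks by signal and 8 against genes with a pooled region nearby. With each summit given to its nearest 5' end within the list's background they numbered 9. With shifted summits 6 lists were bound more often. There rRNA genes reversed (log2 ratio -1.29, permutation test, adjusted p = 0.0009), from 2 of 22 bound without a call by the exact test. Their share of all bound genes was 0.104%, against 0.292% under shifts. Both bound rRNA genes are mitochondrial, where closely spaced summits can keep them bound under shifts. Shifted summits lie by fewer 5' ends, which raises the share of genes that stay bound. This permutation p therefore gives no evidence on rRNA genes. Against genes with a pooled region nearby, 3 lists were bound less often, and the cause was not tested. Lists with a different signal numbered 5 with the 2000 bp window, 4 with nuclear peaks, 3 with peaks supported by both replicates, and 2 to 2 with each replicate alone, against 1; the cause was not tested. Among single lists, genes, peaks and the X ratio split by distance, under all alternatives, 354 values kept their side, 34 fell below the threshold, 6 rose past it, 19 moved and 1 reversed. The 20 kb around ztf-7 held 3.5 pooled regions per 10 kb. Read depth is unknown from the files used, so what it limits could not be assessed. Leaving out a replicate gives no value for the IDR peak count.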

Other observations

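The tests of coverage of the mitochondrial molecule, of X density in pooled regions and of X density per replicate were chosen after the result was seen, as were the sequence word and the split of X peaks by distance. Joining overlapping 6-mers of the summits gave the 13-base word AGAGAGACGCAGA, which lay within 50 bp of 6 of 1289 nuclear IDR summits (0.465%). Trimmed by 1 base at each end it lay near 25 (1.94%). Trimmed by 2 bases at each end, to AGAGACGCA, it lay near 74 (5.74%) and in 1 flank of the same size (0.0776%). Among pooled regions outside the IDR peaks the trimmed 9-base word lay near 0.851% of summits and in 0.394% of flanks. The word was built from the same peaks, so these shares are a description.

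IDR peaks covered 58.7% of mitochondrial DNA and 0.388% of the nuclear genome. Reads shared with exact nuclear copies of mitochondrial DNA are argued against: 0.580% of the mitochondrial bases under IDR peaks lay in 36-base stretches that also occur in a nuclear chromosome. Over the whole molecule the share was 0.341%, a property of the reference sequence. At a coverage of 58.7% the share under peaks could therefore not have been large wherever the peaks lay. The argument rests on how few such stretches the reference holds, not on the peak positions. Nuclear copies with mismatches were not searched, so reads shared with them were not tested. Broad coverage of 58.7% is what more mitochondrial DNA in the ChIP than in the control would give, and remains a candidate explanation. No biological explanation was tested.

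Pooled regions outside the IDR peaks had an X to autosome ratio of 1.13, below the lower limit of 1.36 for IDR peaks. The IDR peaks are the strongest pooled regions, and the ratio was 1.68 in their upper 50% by signal. A rise of signal over all of X could itself give a larger ratio among stronger regions. The lower ratio of the weaker regions therefore cannot exclude a chromosome-wide difference. The excess of IDR peaks on X did not rest on 1 replicate, as the lower of the 2 replicates' lower limits was 1.18. With bases at the same distance as expectation the ratio was 1.36 for peaks within 1000 bp of a coding 5' end and 2.30 for peaks farther away. A chromosome-wide difference may contribute, and no biological explanation was tested.

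The 40 kb around ztf-7 held 2 pooled regions per 10 kb, under the 95th percentile of random windows, 7. An excess of called regions from extra copies of the tagging transgene was thus not seen, but whether extra copies raise that number was not tested, and whether the control carries the same copies is not given in the sources used here. The number of IDR peaks at ztf-7 among the strongest of both replicates was 1, as extra copies placing a strong peak at ztf-7 itself would give. Binding of ZTF-7 at its own gene would give the same peak, and no biological explanation was tested.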
